A study of Homo sapiens with 18 samples.

How the data were processed

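Gene expression was measured in HK-2 cells, an immortalised line of human kidney proximal tubule epithelium, on Illumina HumanWG-6 bead arrays that carry 48803 probes. The 18 arrays came from 18 separate flasks, 1 array each, in 6 groups of 3 flasks. Per the labels' protocols, cells of passages 18 to 30 were kept for 48 h in medium with 5 mM glucose and starved of serum overnight before the agonists were added. Groups were defined by the sample titles: control for 48 h, control for 18 h, transforming growth factor beta 1 (TGF-beta1) at 2 ng/mL for 48 h, C-peptide at 5 nM for 48 h, C-peptide at 5 nM for 18 h, and both agents for 48 h. The 18 h and 48 h incubations ended together, per the labels' protocols. The free-text descriptions of TGF-beta1 replicates 2 and 3 name the growth factor with a different final number, which reads like a numbering slip, and these arrays were kept in the group that their titles give.

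The deposited table of unnormalized values holds, per the file headers, mean bead intensity exported from GenomeStudio version 1.1.1 with no normalization and no error model. Each array's columns were tied to its sample by the header of the table. A background level appeared to have been subtracted before deposit, since 23.4% to 28.1% of the probes on an array had an intensity below 0. The deposited detection values are a fraction, 1 minus the detection p, so that high values mark detected probes. A second deposited table holds the authors' normalized intensity on a linear scale. Its columns share a single distribution, with 99.9% of the sorted values within 0.11 of those of the first array, and each column ranks probes like its own unnormalized array (lowest rank correlation 0.99999). The submitters' processing notes name GenomeStudio and BeadStudio, without saying which step each carried out. The median of every normalized column was 5.0.

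The mean signal per array ranged from 215.9 to 343.7 intensity units, and 14580 to 15818 probes per array were detected at a detection p under 0.01. The median number of beads behind a probe's value was 40 to 42. The number of arrays, 3 per group, limits the precision of every comparison. The median over genes of the SD between replicates was 0.09 on the log2 scale in the 48 h controls, 0.13 in the 18 h controls, 0.11 with TGF-beta1, 0.11 with C-peptide for 48 h, 0.15 with C-peptide for 18 h and 0.10 with both agents.

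Unnormalized intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p, adds an offset of 16, applies quantile normalization and takes log2. Probes detected on 3 or more arrays were kept, and the probe with the highest mean stood for its gene, which left 12468 genes. The probe names in the table were brought to current symbols through a RefSeq gene table. Of the 48803 probes, 22068 carried a current symbol, 5138 an older symbol with a single successor, and 21597 kept the name in the table. Among 3092 genes with at least 2 probes kept, 31 had probes past the threshold in both directions for TGF-beta1.

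Linear models with the 6 group means were fitted to all 18 arrays with limma (lmFit, contrasts.fit and eBayes with an intensity trend), leaving 12 residual degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg over all genes within each comparison, and genes with an adjusted p under 0.05 were called. All values of p for single genes come from this model and are two-sided. The comparisons were TGF-beta1 against control, C-peptide against control at 48 h and at 18 h, both agents against control, against TGF-beta1 and against C-peptide, the interaction of the agents, the difference between the C-peptide changes at 48 h and 18 h, the C-peptide change averaged over its 3 matched comparisons, and the 48 h against the 18 h controls. The size of the TGF-beta1 response with C-peptide was set against that without it by a slope through the origin over genes called for the averaged TGF-beta1 change, with a jackknife standard error (SE) over the 12 arrays at 48 h. The share of TGF-beta1-changed genes that moved the opposite way when C-peptide was added was compared with 100 simulated sets of arrays in which C-peptide added nothing to TGF-beta1.

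A set of 25 gene lists was fixed in advance, covering TGF-beta targets, extracellular matrix, proteases, mesenchymal, epithelial and proximal tubule genes, kidney injury, hepatocyte growth factor (HGF), retinoic acid, PPAR, MAP kinase, NF-kappaB, interferon, cell cycle, p53, cholesterol, amino acid and ER stress, hypoxia, NRF2, heat shock and mitochondrial genes, and markers of fibroblasts, endothelial cells, leukocytes and the distal tubule. The 22 lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01 between genes and again with the correlation estimated per list, with adjustment over the 22 lists. The gene lists, the comparisons, the tests and the rule for naming genes were chosen before the data were examined. That rule took, per comparison, the 6 highest and the 6 lowest fold changes among called genes whose 3 arrays of each group did not overlap (a condition dropped for averages and interactions), up to 3 called members per list with the largest changes, and 16 core genes whatever their p. Where fewer than 10 genes were called, it took the 5 highest and 5 lowest test statistics. Genes with no symbol beyond a LOC or HS identifier were counted and not named, and the text names a part of the genes the rule gave.

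A gene below detection on all 3 arrays of a group has only a bound there. Its fold is given as at least N-fold, from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the probe's own signal, with the adjusted p of the model. The fits were tested on simulated data built from the mean of each gene over all arrays and its residual SD, with 200 of the 12468 genes changed. Of simulated changes of 0.5 on the log2 scale 55.2% were recovered, of changes of 1 98.5% and of changes of 2 100%, and 12 calls were false. A simulated slope of 0.8 was recovered as 0.79.

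The alternatives were the authors' normalized values on the log2 scale, quantile normalization without background modelling, median scaling, no filter on dim probes, detection on all 18 arrays, the mean over a gene's probes, no intensity trend, estimated array weights, the replicate number as a block, the arrays of the compared groups alone, each array left out in turn, and for lists an estimated correlation and fry. The fits with 1, 2 or 3 components of the variation within groups as covariates, and 10 repeats of the simulated draws with other random seeds, were chosen after seeing the data. A chip as a block was planned and was not run, since the column names give no chip. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.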

Results

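The series asked how C-peptide, the fragment released when proinsulin is cut to insulin, and TGF-beta1, a growth factor that drives fibrosis, act on gene expression of human proximal tubule cells, alone and together. HK-2 cells were profiled in 6 groups of 3 flasks: controls and C-peptide (5 nM) at 18 h and 48 h, TGF-beta1 (2 ng/mL) at 48 h, and both agents at 48 h. The 18 arrays detected 14580 to 15818 of 48803 probes each, and 12468 genes were tested. For TGF-beta1 5622 genes were called, and for C-peptide 663 at 48 h, 286 at 18 h and 268 in cells that also received TGF-beta1. At 48 h the arrays with C-peptide form a separate consecutive set of array numbers, so the 663 and 268 calls cannot be assigned to C-peptide alone. The 286 calls fell to 0 when only the arrays compared were fitted.

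**Figure D1:**
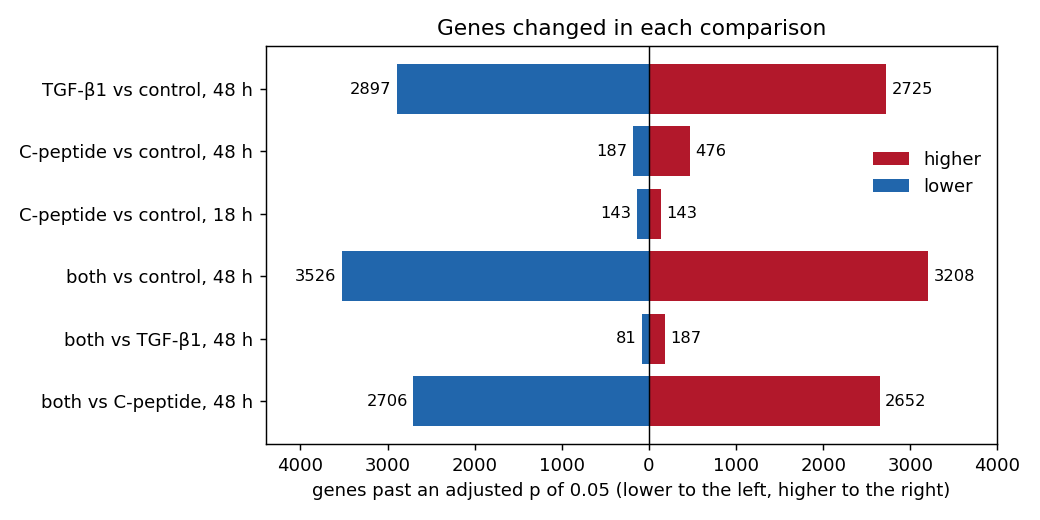
Number of genes (horizontal axis) past an adjusted p of 0.05 in 6 comparisons of 3 against 3 arrays, lower genes in blue to the left and higher genes in red to the right. The comparisons that add TGF-beta1 call between 5358 and 6734 genes, and those that add C-peptide between 268 and 663.

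TGF-beta1 for 48 h raised the lists of matrix and protease genes and lowered those of epithelial and proximal tubule genes, and the largest single changes went both ways. AMTN, which encodes the mineral-associated protein amelotin, was at least 23.9-fold higher (adjusted p = 4.97e-14), and TNFAIP6, a hyaluronan-binding protein, rose by 5.02 on the log2 scale (SE 0.40, adjusted p = 3.41e-09). SCG5, a chaperone of the prohormone convertase pathway, rose by 4.38 (SE 0.26). The chorionic gonadotropin beta genes CGB5 and CGB1 were at least 15.6-fold and 12.7-fold higher, although these near-identical copies share sequence and their separate levels are uncertain. DEPTOR, an inhibitor of mTOR, fell by 4.46 on the log2 scale (SE 0.24, adjusted p = 9.11e-12), and CRISPLD2, a secreted protein, fell by 4.37 (SE 0.34). FXYD2, the gamma subunit of the sodium pump, fell by 3.83 (SE 0.17) and MAL, a protein of apical membrane traffic, fell by 3.49 (SE 0.41). The proteoglycan SPOCK2 was at least 13.6-fold lower and LCN2, a marker of tubular injury, at least 10.5-fold lower (n = 3 arrays per group, limma).

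Genes that TGF-beta signalling is known to induce were among those that rose. Of 22 measured TGF-beta target and feedback genes, 14 rose, 2 fell and 6 did not pass, the same 14 and 2 when adjusted over the list alone, and the list was higher than other genes (camera adjusted p = 6.93e-08). The membrane adaptor PMEPA1 rose by 2.42 on the log2 scale (SE 0.11), the matrix protein TGFBI by 2.15 (SE 0.10) and the inhibitory SMAD7 by 1.80 (SE 0.16). CCN2, a frequently used readout of TGF-beta, differed by -0.01 (SE 0.10, adjusted p = 0.939) and did not pass. Of 27 genes of the extracellular matrix and its crosslinking, 22 rose, 2 fell and 3 did not pass, or 23 and 2 adjusted over the list alone (camera adjusted p = 8.91e-08). The collagen-crosslinking oxidase LOX rose by 2.94 (SE 0.22), COL1A1 by 2.32 (SE 0.12) and COL4A1 by 0.89 (SE 0.10), and COL6A3 was at least 2.39-fold higher. FN1, which encodes fibronectin, rose by 0.77 (SE 0.30, adjusted p = 0.0402), and this call was lost when any of the 6 arrays was left out (highest adjusted p = 0.106).

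Of 14 matrix proteases and inhibitors, 8 rose, 2 fell and 4 did not pass, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00588). The collagenase MMP1 was at least 9.82-fold higher, the stromelysin MMP10 at least 4.92-fold higher, and the gelatinase MMP9 rose by 3.08 (SE 0.20). Among 21 mesenchymal and contractile genes 12 rose, 1 fell and 8 did not pass, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00063). WNT5A rose by 2.09 (SE 0.21), the actin-binding TAGLN by 1.55 (SE 0.17) and VIM, vimentin, by 0.44 (SE 0.06). The member that fell was ACTA2, smooth muscle actin, at -0.36 (SE 0.11, adjusted p = 0.011), a call lost without control replicate 1 (adjusted p = 0.071). SNAI2, a repressor of epithelial genes, differed by 0.12 (SE 0.15, adjusted p = 0.548).

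Epithelial genes fell as a group, with 12 of 19 lower, 4 higher and 3 not passing, the same 12 and 4 adjusted over the list alone (camera adjusted p = 0.00104). CDH1, the epithelial cadherin, fell by 3.06 on the log2 scale (SE 0.18, adjusted p = 2.68e-11) and the epithelial transcription factor ELF3 by 2.67 (SE 0.10), while the desmosomal DSP rose by 2.65 (SE 0.11). Of 13 proximal tubule function genes 8 fell, 3 rose and 2 did not pass, with the same counts of 8 and 3 adjusted over the list alone (camera adjusted p = 0.00588). The bicarbonate cotransporter SLC4A4 fell by 1.63 on the log2 scale (SE 0.15) and PAX8, a renal transcription factor, by 1.37 (SE 0.13), and the glucose transporter SLC2A2 was at least 2.72-fold lower. Cell cycle genes rose, with 22 of 32 higher, 4 lower and 6 not passing, the same 22 and 4 adjusted over the list alone (camera adjusted p = 3.93e-09). The mitotic kinase AURKB rose by 1.53 (SE 0.12), the ubiquitin-conjugating UBE2C by 1.43 (SE 0.08) and cyclin CCNA2 by 1.38 (SE 0.08). Interferon-stimulated genes fell, with 15 of 21 lower, 1 higher and 5 not passing, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00133). IFIT2 fell by 1.15 on the log2 scale (SE 0.16) and the RNA sensor RIGI by 0.87 (SE 0.12), whereas IFI44L rose by 0.89 (SE 0.13).

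A pair of lists passed only at the preset correlation. Among 28 MAP kinase and immediate early genes 14 rose, 5 fell and 9 did not pass, with the same 14 and 5 adjusted over the list alone (camera adjusted p = 0.00313, adjusted p = 0.0701 with an estimated correlation). The early transcription factors EGR2, JUNB and FOSB rose by 3.61 (SE 0.15), 2.21 (SE 0.14) and 1.60 (SE 0.12). Among 16 retinoic acid signalling genes 9 fell, 3 rose and 4 did not pass, the same 9 and 3 adjusted over the list alone (camera adjusted p = 0.0402, adjusted p = 0.186 with an estimated correlation). The retinoid-inducible PLAAT4 fell by 3.32 (SE 0.11) and RARRES2 by 2.61 (SE 0.12), the retinaldehyde reductase DHRS3 was at least 2.48-fold lower, and CRABP2, a retinoic acid carrier, differed by -0.03 (SE 0.28, adjusted p = 0.945). The other 8 lists that passed also passed with an estimated correlation (adjusted p of 0.00552 to 0.0404).

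The remaining lists did not pass as sets. Of 16 kidney injury genes 4 rose and 8 fell (camera adjusted p = 0.216), among them SOX9, a regenerative transcription factor, at least 7.94-fold higher, and annexin ANXA1, which fell by 1.60 on the log2 scale (SE 0.13). Of 20 HGF signalling genes 6 rose and 2 fell (adjusted p = 0.192), with integrin ITGA2 rising by 1.76 (SE 0.16) and the receptor MET at 0.11 (SE 0.12, adjusted p = 0.489). HGF and the retinoic acid receptor RARB were detected on 0 arrays and were not tested. Growth arrest and p53 targets gave 3 higher and 10 lower of 20 (adjusted p = 0.179), with the cell cycle inhibitor CDKN1A at 0.15 (SE 0.12, adjusted p = 0.35). NF-kappaB targets gave 1 higher and 7 lower of 19 (adjusted p = 0.214) and PPAR targets 2 higher and 5 lower of 15 (adjusted p = 0.242). Amino acid and ER stress genes gave 7 higher and 7 lower of 23 (adjusted p = 0.833), with a mean of 0.01 and a median of -0.05. Hypoxia and glycolysis genes gave 7 higher and 5 lower of 21 (adjusted p = 0.854), with a mean of -0.13 and a median of 0.02, and cholesterol genes 2 higher and 4 lower of 22 (adjusted p = 0.912), with a mean of -0.05 and a median of 0.05. NRF2 and metallothionein genes gave 6 higher and 3 lower of 20 (adjusted p = 0.523), heat shock genes 4 and 1 of 12 (adjusted p = 0.169) and respiratory chain genes 6 and 1 of 28 (adjusted p = 0.201). Adjusted over the list alone, these counts differed only for NF-kappaB targets (2 and 7), ER stress genes (9 and 8) and cholesterol genes (2 and 3).

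Markers of other cell types moved with TGF-beta1 in single genes. Fibroblast markers gave 3 higher and 1 lower of 7 (camera adjusted p = 0.192). Among markers of endothelial cells, leukocytes and the distal tubule, 3, 2 and 2 were measured, too few for a set test. PECAM1 was at least 1.17-fold higher and the macrophage receptor CSF1R at least 3.82-fold higher, while the sodium channel subunit SCNN1A was at least 5.44-fold lower and the proton pump subunit ATP6V1B1 at least 1.30-fold lower. In total 2725 genes were higher and 2897 lower, 368 and 483 of them by at least 2-fold. Of 56 genes named here for TGF-beta1, 51 passed.

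**Figure D2:**
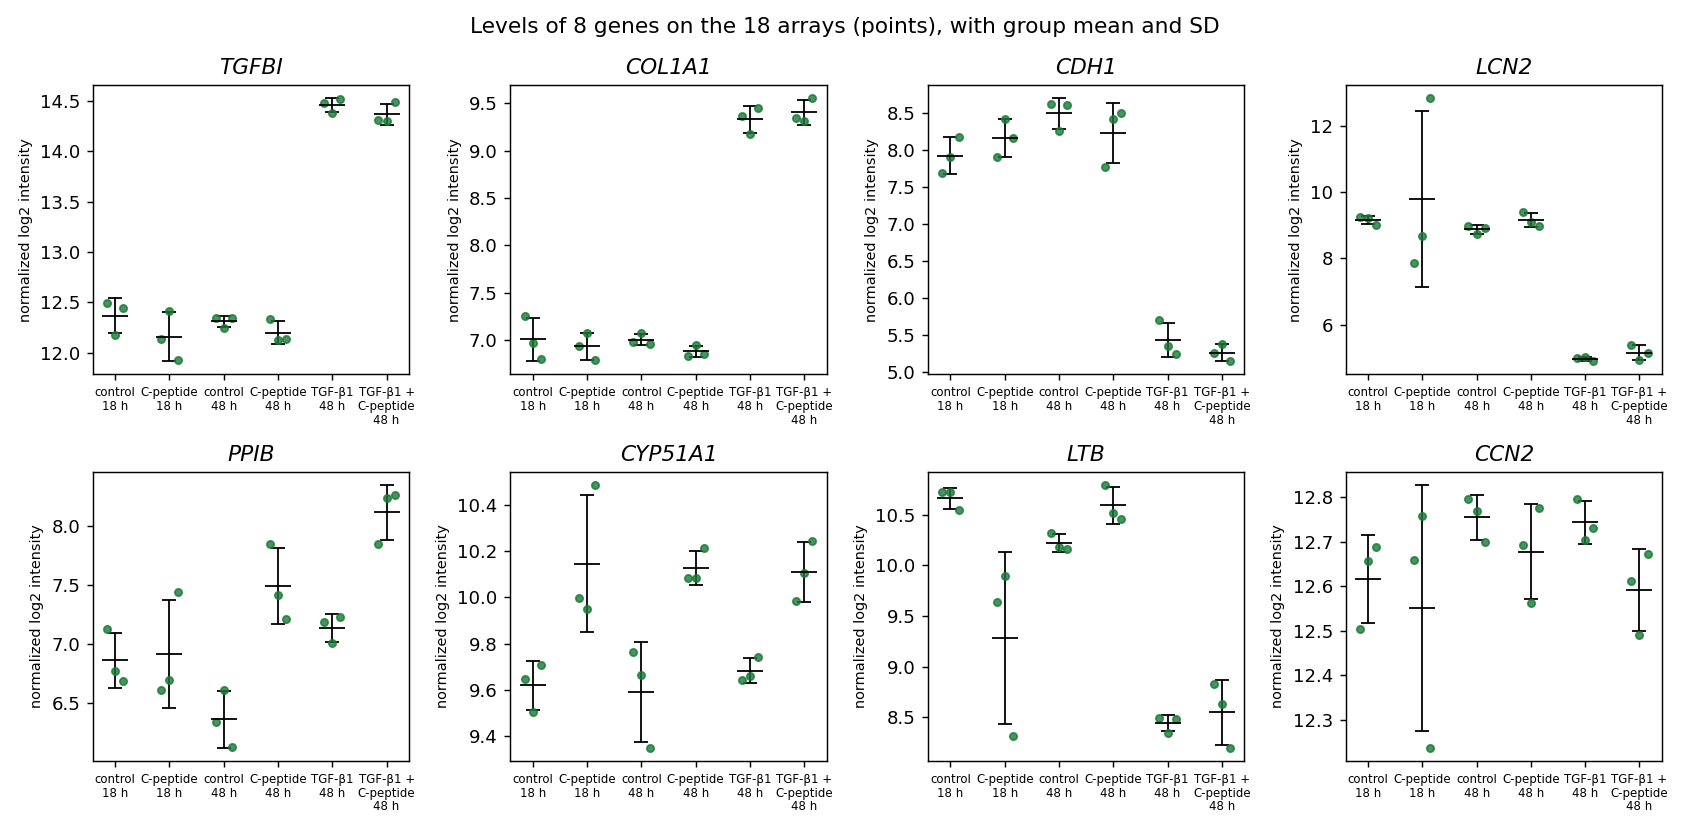
Normalized log2 intensity (vertical axes) of 8 genes on the 18 arrays (points) in 6 groups of 3, with the mean and SD of each group as bars. TGFBI and COL1A1 sit higher and CDH1 and LCN2 lower in both TGF-beta1 groups, and on C-peptide 18 h replicate 3 LCN2 reaches 12.83 against 7.87 and 8.66 on the other replicates.

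C-peptide alone for 48 h gave small changes. PTMA, which encodes the nuclear protein prothymosin alpha, rose by 1.07 on the log2 scale (SE 0.08, adjusted p = 5.7e-07), the actin-capping subunit CAPZA1 by 1.16 (SE 0.11), the DNA repair phosphodiesterase TDP2 by 1.14 (SE 0.15) and the ER-resident cyclophilin PPIB by 1.13 (SE 0.20). SUCO, an ER membrane protein, rose by 0.99 (SE 0.16), and HLA-G by 1.04 (SE 0.12), although its probe may be shared with other HLA class I genes. The nuclear receptor NR2C2 fell by 0.75 (SE 0.21, adjusted p = 0.0417), the guanine exchange factor RAPGEF6 by 0.71 (SE 0.17), the Hippo pathway kinase LATS2 by 0.62 (SE 0.16) and the drug efflux pump ABCB1 by 0.61 (SE 0.13). Replication and matrix genes had called members that fell, 3 of 32 cell cycle genes (CDC6 by 0.46, MCM4 by 0.44 and MCM3 by 0.27) and 3 of 27 matrix genes (COL8A1 by 0.48, THBS1 by 0.42 and SPARC by 0.35). Adjusted over the list alone, 2 cell cycle genes were higher and 4 lower, and 3 matrix genes were lower. The cholesterol genes CYP51A1 and STARD4 rose by 0.54 (SE 0.12) and 0.58 (SE 0.16), as did the growth arrest gene CDKN1B by 0.48 (SE 0.11) and the p53 target PMAIP1 by 0.60 (SE 0.12).

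Of 663 genes called for C-peptide at 48 h, 476 were higher and 187 lower, and 12 were at least 2-fold higher. This balance depended on the fit, with 1404 higher and 1735 lower with array weights, 747 and 560 with its own groups alone, and 562 and 446 without C-peptide replicate 3. It moved the other way in the remaining fits that left out an array, with 360 and 39, 255 and 25, and 215 and 23 without control replicates 1, 2 and 3, and 188 and 8, and 289 and 47 without C-peptide replicates 1 and 2. Identifiers without a proper symbol made up 31.3% of the higher genes and 11.6% of all genes tested. None of the 14 measured core genes passed (0 in limma, lowest adjusted p = 0.176), and 0 of 22 lists passed camera, 2 of them at an unadjusted p under 0.05 (lowest adjusted p = 0.437). The count rested on single arrays, with 399, 280 and 238 genes without control replicates 1, 2 and 3, 196 and 336 without C-peptide replicates 1 and 2, and 1008 without C-peptide replicate 3. Of the 20 genes named, CAPZA1, TDP2, PPIB, PTMA, HLA-G, SUCO and PMAIP1 (7 genes) kept an adjusted p under 0.05 in every such fit. The SD of 31728 probes detected on no array was 6.06 to 6.69 intensity units on the control and TGF-beta1 arrays at 48 h and 3.98 to 5.47 on the arrays with C-peptide at 48 h. At 48 h all arrays with C-peptide carried array numbers in a separate consecutive set of 6, so C-peptide and array set cannot be told apart there.

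C-peptide for 18 h called 143 genes higher and 143 lower, or 88 and 151 with median scaling. Of 22 cholesterol genes 5 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 5.18e-05, adjusted p = 0.903 with an estimated correlation). The list mean stood at 0.44 on C-peptide replicate 3, which carried an inflammatory signature, and at 0.11 and 0.03 on replicates 1 and 2, and the list change of 0.24 was 0.12 without replicate 3. INSIG1, a sterol sensor partner, rose by 0.62 on the log2 scale (SE 0.09, adjusted p = 0.00658), the sterol transporter STARD4 by 0.71 (SE 0.16) and the sterol demethylase CYP51A1 by 0.53 (SE 0.12). The Golgi mannosidase MAN2A1 rose by 0.92 (SE 0.20), the R-spondin receptor LGR4 by 0.86 (SE 0.22), the laminin LAMA1 by 0.85 (SE 0.22) and DUSP6, a phosphatase of ERK, by 0.79 (SE 0.16). The ubiquitin-like UBD fell by 1.53 (SE 0.36, adjusted p = 0.0384), lymphotoxin LTB by 1.38 (SE 0.25), the cytokine subunit IL23A by 1.03 (SE 0.27), keratin KRT7 by 0.94 (SE 0.17), MMP9 by 0.92 (SE 0.20) and TAGLN by 0.86 (SE 0.17). LTB stood at 9.64, 9.90 and 8.31 on C-peptide replicates 1, 2 and 3, against 10.72, 10.72 and 10.54 on the controls, so replicate 3 enlarged its fall. NF-kappaB targets had 0 called members of 19 (limma) and a mean of 0.39, and the list did not pass camera. Without C-peptide replicate 3 the mean was -0.22 and the list passed (camera adjusted p = 0.00626 at the preset correlation). The list stood at -0.25 and 0.01 on C-peptide replicates 1 and 2, against 0.10, 0.13 and 0.06 on the controls. Replicate 1 thus carried most of this fall, and that fit was not run with an estimated correlation. Of 14 core genes 0 passed (lowest adjusted p = 0.0808), with CRABP2 at -0.72 and FN1 at 0.58 as the extremes. Without C-peptide replicate 3 FN1 stood at -0.0105. The 286 calls were not stable to single arrays, with 0, 1 and 1780 without control replicates 1, 2 and 3, 1327 without C-peptide replicate 1 and 79 without C-peptide replicate 3, and none of the 13 called genes named kept its call in every such fit.

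In cells given TGF-beta1, adding C-peptide again raised PTMA, by 0.85 on the log2 scale (SE 0.08, adjusted p = 3.18e-05), and PPIB, by 0.98 (SE 0.20). The respiratory chain subunit NDUFA5 rose by 0.89 (SE 0.16) and COX7B by 0.35 (SE 0.07), the growth factor GDF6 was at least 1.53-fold higher, and CDKN1B rose by 0.56 (SE 0.11). The kinases TAOK1 and LATS2 fell by 0.84 (SE 0.21) and 0.66 (SE 0.16), the zinc finger gene RBAK by 0.75 (SE 0.14), the DNA polymerase subunit POLD1 by 0.63 (SE 0.16) and the chaperone HSPA8 by 0.35 (SE 0.07). Of 27 matrix genes 1 fell, COL8A1 by 0.53 (SE 0.12), or 2 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.783 with an estimated correlation). Of 32 cell cycle genes 2 fell, MCM4 by 0.43 (SE 0.09) and RRM2 by 0.44 (SE 0.11), or 4 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.783 with an estimated correlation). Of 14 core genes 0 passed in limma (lowest adjusted p = 0.304), the extremes being FN1 at -0.48 and CRABP2 at 0.15. Of 268 genes called, 187 were higher and 81 lower, against 445 and 92 with median scaling, 692 and 734 with array weights, and 477 and 378 with its own groups alone. Of the 187 higher genes, 48.1% were identifiers without a proper symbol, against 11.6% of all genes tested. Most of the lower calls were lost when an array was left out, with 20, 2 and 37 lower without TGF-beta1 replicates 1, 2 and 3, and 16, 7 and 22 without replicates 1, 2 and 3 of both agents. Fewer were called without any 1 array, 103, 52 and 172 without TGF-beta1 replicates 1, 2 and 3 and 108, 53 and 92 without replicates 1, 2 and 3 of both agents, and PTMA, NDUFA5 and GDF6 kept their calls throughout.

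The C-peptide changes at 48 h without and with TGF-beta1 share no array and overlapped. Both compare the same consecutive sets of array numbers, so a difference between these sets could also give such an overlap. Of their calls 172 were shared, 152 higher and 20 lower in both and 0 in opposite directions, where independent lists would share 7.14 and 1.21. Across genes, which are not independent replicates, the changes correlated at r = 0.689. The change at 48 h shared 17 calls with that at 18 h, 9 higher in both and 8 in opposite directions (r = -0.13 across genes).

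**Figure D3:**
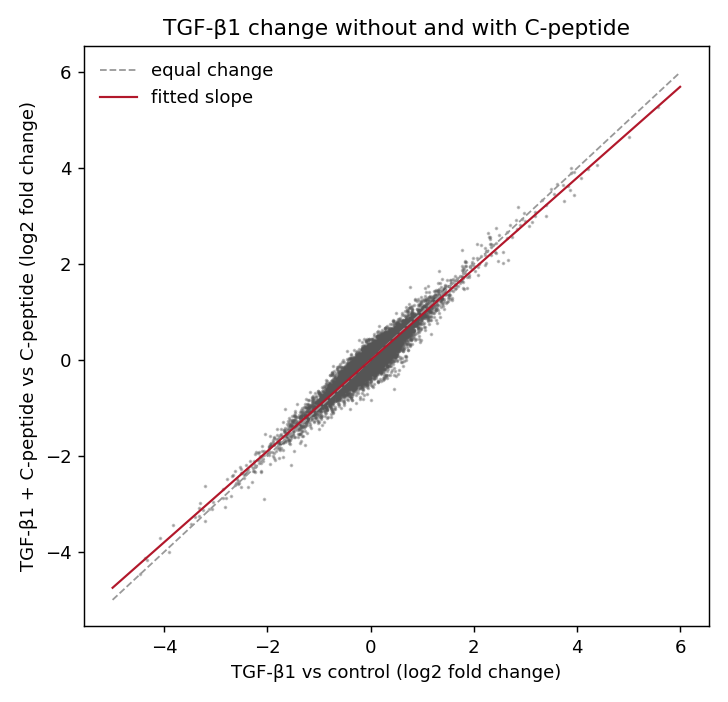
Log2 fold change of TGF-beta1 against control (horizontal axis) and of both agents against C-peptide (vertical axis) for 12468 genes (points), with the line of equal change dashed and the fitted slope of 0.95 in red. Points lie along both lines.

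The response to TGF-beta1 was close in size with and without C-peptide. Each response was measured within its own consecutive set of array numbers. A C-peptide effect on this response, or its absence, cannot be told apart from a difference in scale between the sets. The slope of the TGF-beta1 changes with C-peptide on those without was 0.95 (jackknife SE 0.043) over 7193 genes, and the changes correlated at r = 0.976 across these genes, which are not independent replicates. For the interaction limma called 0 genes, with 388 at an unadjusted p under 0.05. The extreme test statistics included ITPKC, an inositol phosphate kinase, at -0.69 (SE 0.16), and GDF6, both at an adjusted p of 0.999, and GDF6 is given no value since it was below detection in every group but that with both agents. Cholesterol genes differed as a set with no called member (camera adjusted p = 0.0462, adjusted p = 0.871 with an estimated correlation). Of the 5622 genes called for TGF-beta1, 44.9% moved against their TGF-beta1 change when C-peptide was added. Simulated arrays without any C-peptide effect gave 58.0% on average (SD 8.62), and 95 of 100 draws were at or above the observed share, against 85 to 93 in 10 repeats with other random seeds, chosen after seeing the data. These draws also held no difference between the sets of array numbers, and the TGF-beta1 and both-agent arrays lie in different sets. The observed share and the counts that follow therefore cannot be assigned to C-peptide alone. Adjusted over these genes alone, 109 passed for C-peptide, 28 of them against their TGF-beta1 change. That count was not stable, with 208 and 69 of these opposing under median scaling, 675 and 261 with its own groups alone, 806 and 350 with array weights, and 220 and 87 with 1 component of the variation within groups as a covariate. It was 70 and 68 without control replicates 2 and 3, 51, 23 and 44 without TGF-beta1 replicates 1, 2 and 3, and 55, 22 and 47 without replicates 1, 2 and 3 of both agents. In the simulated draws the median of this count was 0 and the highest 791, and 1 draw reached 109. The highest count depended on the seed, from 0 to 1224 in the 10 repeats, in which 0 to 2 of 100 draws reached 109.

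Both agents together against control gave the TGF-beta1 picture again. The control arrays and those with both agents lie in different consecutive sets of array numbers. Any difference between these sets is thus part of this comparison. AMTN was at least 26.9-fold and MMP1 at least 15.1-fold higher, TNFAIP6 rose by 5.17 on the log2 scale (SE 0.40), SCG5 by 4.68 (SE 0.26), the forkhead factor FOXS1 by 4.31 (SE 0.20) and TGFBI by 2.05 (SE 0.10). CRISPLD2 fell by 4.52 on the log2 scale (SE 0.34), DEPTOR fell by 4.49 (SE 0.24) and SPOCK2 fell by 4.02 (SE 0.49), and LCN2 and CDH1 were at least 11.1-fold and 8.49-fold lower. In all 6734 genes were called, 3208 higher and 3526 lower, or 3755 and 3074 with median scaling. Of 22 lists 11 passed camera and 3 of these also with an estimated correlation (lowest adjusted p = 0.0174 with an estimated correlation). Against C-peptide alone, 5358 genes were called, 2652 higher and 2706 lower (2977 and 2400 with median scaling), with AMTN at least 25.1-fold higher, CDH1 at least 7.06-fold lower, and TGFBI and SMAD7 higher by 2.17 (SE 0.10) and 1.89 (SE 0.16). Of 22 lists 9 passed, 8 of them with an estimated correlation (lowest adjusted p = 0.00574 with an estimated correlation). The calls of TGF-beta1 without and with C-peptide, which share no array, had 4420 genes in common, 1 of them in opposite directions.

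The C-peptide changes at 48 h and 18 h differed for 1112 genes, 530 with a higher and 582 with a lower change at 48 h. LTB differed by 1.75 on the log2 scale (SE 0.35, adjusted p = 0.0113), HLA-G by 1.29 (SE 0.17), the checkpoint kinase ATR by 1.49 (SE 0.45) and the actin-binding COTL1 by 1.28 (SE 0.34). C-peptide 18 h replicate 3 enlarged the LTB difference, with LTB at 8.31 there against 9.64 and 9.90 on replicates 1 and 2. The transcription factor SIM1 differed by -1.39 (SE 0.41), MAN2A1 by -1.32 (SE 0.29), LAMA1 by -1.29 (SE 0.31), RAPGEF6 by -1.17 (SE 0.25) and LGR4 by -1.15 (SE 0.31). With median scaling 761 changes were higher and 549 lower. The count was 540, 655 and 326 without 48 h control replicates 1, 2 and 3, 171, 285 and 2475 without 18 h control replicates 1, 2 and 3, and 192 and 580 without 48 h C-peptide replicates 1 and 2, and LTB, HLA-G and RAPGEF6 kept their calls throughout.

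The C-peptide change averaged over its 3 matched comparisons passed for 796 genes, 555 higher and 241 lower, 0 of them by 2-fold. With array weights 726 were higher and 476 lower. With an array left out, 438 to 631 were higher and 100 to 403 lower, the extremes for the lower genes being without 48 h C-peptide replicates 1 and 3. The number of lower genes was also 144, 111 and 150 without 48 h control replicates 1, 2 and 3, 158 without 18 h control replicate 3, 112 and 112 without TGF-beta1 replicates 1 and 2, 133 without 48 h C-peptide replicate 2, 374 without 18 h C-peptide replicate 1, and 109 and 159 without replicates 2 and 3 of both agents. PTMA rose by 0.69 on the log2 scale (SE 0.05, adjusted p = 6.39e-08), TDP2 by 0.73 (SE 0.09) and PPIB by 0.72 (SE 0.11). STARD4 and CYP51A1 rose by 0.52 (SE 0.09) and 0.50 (SE 0.07), with 4 of 22 cholesterol genes higher, or 5 adjusted over the list alone (camera adjusted p = 0.0247, adjusted p = 0.831 with an estimated correlation). LATS2 fell by 0.38 (SE 0.09), COL8A1 by 0.37 (SE 0.07) and the membrane protein LRRN4 by 0.37 (SE 0.07). The changes at 18 h were looked up after the average was seen. Those of PTMA at 0.17, TDP2 at 0.39, PPIB at 0.05, LATS2 at 0.12 and COL8A1 at -0.10 did not pass (adjusted p of 0.117 to 0.901). All were smaller in size than at 48 h, where C-peptide coincides with the sets of array numbers, and LATS2 had the opposite sign. CYP51A1, STARD4 and LRRN4 passed at 18 h as well, but the 18 h comparison called 0 genes without control replicate 1. The 18 h calls of CYP51A1 and STARD4 were each lost in 3 of 6 fits that left out an array. For the average, all 8 genes named here kept their calls whichever array was left out. The controls at 48 h and 18 h differed in 1 gene, RABL2A, a small GTPase of cilia, which differed by -0.70 (SE 0.11, adjusted p = 0.0228), with 2740 genes at an unadjusted p under 0.05. Without 18 h control replicate 3 the count was 1568, and without any other control array it was 0.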

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

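The tests of a single array and of variation within groups were chosen after the result was seen, and the draws of other groupings before. The C-peptide change at 48 h differed from that at 18 h for 1112 genes in a direct test of the difference (limma). Of 100 groupings drawn within each matched pair of groups, the real one included, 1 gave as many genes and the highest other gave 583. Random groupings within pairs thus rarely reached the count. They also break up the change at each time, so they do not test whether the changes at both times were equal. Without C-peptide 18 h replicate 3, whose inflammatory genes stood apart, 1558 genes were called, which argues against that flask as the sole source. With 2 components of the variation within groups as covariates 7 genes were called, with 1 component 2151 and with 3 components 10. With 2 components the median absolute difference of the 1112 genes went from 0.61 to 0.38 on the log2 scale while the median SE went from 0.16 to 0.17, so the calls ended mainly because the differences shrank. The covariates were array scores that also hold differences between groups, so some of this shrinkage can follow from their construction. Whether a direction of variation within groups accounts for part of the difference is therefore undecided. A change of the C-peptide effect with time stays open. The direct comparison is also open to the sets of arrays described under the other observations, since at 48 h the C-peptide and control arrays lie in different sets. At 18 h both lie in the same set.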

How the results depend on the processing

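The fits with components of the variation within groups as covariates were chosen after seeing the data. The counts for TGF-beta1 and for both agents against C-peptide stayed within 1.5 times under every alternative, and the slope of 0.95 stayed between 0.93 and 0.98. Both agents against control moved only with 2 or 3 components (4194 and 4165 against 6734), and the share of TGF-beta1 changes opposed by C-peptide only with 2 or 3 components (54.2% and 56.0% against 44.9%). For the counts below the cause was not tested, except that leaving out arrays or groups leaves fewer samples. C-peptide at 48 h (663) gave 3139 with array weights (1404 higher and 1735 lower), 1129 with 1 component, 421 with 3 and 1307 with its own groups alone, and 196 to 1008 with an array left out. C-peptide at 18 h (286) gave 17 with no filter on dim probes, 1124 with array weights, 0 with 2 components, 14 with 3 and 0 with its own groups alone, and 0 to 1780 with an array left out. With median scaling its split was 88 higher and 151 lower against 143 and 143. Both agents against TGF-beta1 (268) gave 537 with median scaling (445 higher and 92 lower), 165 with no filter, 1426 with array weights (692 and 734), 590 with 1 component and 855 with its own groups alone, and 52 to 172 with an array left out. The interaction (0) gave 1 with 3 components. The difference between 48 h and 18 h (1112) gave 480 with no filter, 3365 with array weights, 2151, 7 and 10 with 1, 2 and 3 components and 237 with its own groups alone, and 171 to 2475 with an array left out. The C-peptide average (796) gave 1202 with array weights and 538 to 1016 with an array left out. The controls (1) gave 2 without background modelling, 126 with median scaling, 0 with no filter, 5 with the mean over probes, 2 without an intensity trend, 2917 with array weights, 659, 0 and 4 with 1, 2 and 3 components and 136 with their own groups alone, and 0 to 1568 with an array left out.

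Fits with the replicate number as a block gave 547 genes for C-peptide at 18 h and 86 for the controls, and moved no other count by over 1.5 times. The numbers did not pair the flasks: over 45 pairs of arrays with the same number the deviations correlated at -0.34 to 0.28, with 14 pairs over 0.1, and 3 of 18 arrays correlated best with their own number. A chip as a block was not run. Of 2910 refits of named genes 2571 kept direction and side of the threshold, 304 lost their call, 10 gained one and 25 changed sign. The sign changes were CCN2 with TGF-beta1 (0.18, 0.18 and 0.20 with 1, 2 and 3 components, 0.00934 without control replicate 1 and 0.00850 without TGF-beta1 replicate 2, and -0.0391 to 0.00934 over single arrays), CRABP2 with TGF-beta1 (0.61, 0.45 and 0.44 with 1, 2 and 3 components, 0.0624 without control replicate 1 and 0.0473 without TGF-beta1 replicate 2, and -0.117 to 0.0624 over single arrays), CDKN1A with TGF-beta1 (-0.00808 with 2 components) and GDF6, mostly below detection, in the interaction (-0.39 without background modelling). For C-peptide at 18 h the sign changes, all of genes that had not passed, were FN1 (-0.197 and -0.208 with 2 and 3 components, and -0.0105 without C-peptide replicate 3 to 1.00 over single arrays), PPIB (-0.155 with array weights, -0.169 with 1 component, and -0.215 to 0.202 over single arrays), LATS2 (-0.0552 and -0.0901 with 2 and 3 components, and -0.0222 to 0.274 over single arrays) and COL8A1 (0.0265 with the mean over probes, 0.0103 with array weights, and -0.230 to 0.0156 over single arrays). Of 442 refits of lists 391 kept direction and side, 20 lost their call, 22 gained one and 9 changed sign. With TGF-beta1, the mean of the amino acid and ER stress list was -0.0834 with 2 components and -0.00706 to 0.0422 without single arrays, below 0 without control replicates 1 and 3 and TGF-beta1 replicate 1, that of the NRF2 list was -0.18 and that of the respiratory chain list -0.0147 with 2 components. For C-peptide at 18 h the mean of the NF-kappaB list was -0.0889 with array weights and -0.129 with 2 components (camera adjusted p = 0.0303). Over single arrays it ran from -0.219 without C-peptide replicate 3 (camera adjusted p = 0.00626) to 0.758 without C-peptide replicate 1.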

Other observations

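The tests of array sets, signal level, near-identical transcripts and a mislabelled array were chosen after the results were seen. C-peptide 18 h replicate 3 carried an inflammatory signature that no other array showed. The mean deviation of the NF-kappaB list was 1.70 on that array, -0.25 and 0.01 on the other replicates, and at most 0.19 elsewhere. The following genes were chosen after their values were seen. The cytokine IL6 stood at 11.34 on the log2 scale against 7.19 and 7.33 on the other replicates and at most 8.10 on any other array, the chemokine CXCL2 at 10.85 against at most 7.66, and the growth factor CSF2 at 9.98 against at most 7.67. The mitochondrial dismutase SOD2 stood at 13.28 against at most 11.02 and the NF-kappaB inhibitor NFKBIA at 12.86 against at most 11.94. The chemokine CXCL8 was bright on every array, at 14.69 on that one and at most 14.31 on those outside its group.

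A mislabelled TGF-beta1 array would lie near the TGF-beta1 change, yet this array lay 0.118 of the way from the 18 h controls to it, which argues against that label. RNA from leukocytes would bring further markers, yet 1 of 14 leukocyte markers was detected on this array. That was CD68, which all 18 arrays detected and which was highest here (11.15 against at most 10.62 on any other array), while the abundant leukocyte genes PTPRC, LYZ and TYROBP were detected on 0 arrays. A local stimulus to that flask stays open, and no biological explanation was tested, since the design gives none for a single flask.

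The C-peptide change at 48 h appeared alike in both TGF-beta1 backgrounds, with 97.1% of the calls made without TGF-beta1 moving the same way with it. Along the 268 genes called for C-peptide in TGF-beta1-treated cells, arrays with C-peptide alone at 48 h lay 0.51 above their controls on the log2 scale (SE 0.068), and arrays with C-peptide at 18 h lay -0.03 from theirs (SE 0.061). The array numbers place the arrays without C-peptide at 48 h, those with C-peptide at 48 h and the 18 h arrays in 3 consecutive sets of 6. A difference between such sets could contribute, since the untreated 18 h controls lay 0.264 above the untreated 48 h controls along the same genes (SE 0.067), and at 48 h the sets coincide with C-peptide, so they cannot be separated. A lower signal level alone is argued against by the 18 h controls, which had as little background spread as the 48 h C-peptide arrays yet lay -0.25 from them (SE 0.083). The 171 genes with a proper symbol alone differed by 0.45 (SE 0.063), so identifiers without one did not carry the change alone. Probes of genes with a symbol can also be shared, so near-identical transcripts stay open.

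Other groupings of the same arrays were counted for each comparison. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 5622 and 0 for TGF-beta1, 663 and 0 for C-peptide at 48 h, 6734 and 0 for both agents against control, 268 and 0 against TGF-beta1, 5358 and 0 against C-peptide, and 1 and 0 for the controls, so that 1 split reached the real count in each. For C-peptide at 18 h the real count was 286 and another split gave 320, so that 2 splits reached it. For the interaction the real count was 0, which all 100 drawn groupings reach by construction (highest other 242), so these draws say nothing about chance. For the C-peptide average 1 of 100 groupings, the real one, reached 796 and the highest other gave 1, so random groupings rarely reach this count. These draws cannot separate C-peptide from the array sets, which coincide with it at 48 h.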
